A study of Homo sapiens with 18 samples.

How the data were processed

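RNA was measured on 18 Affymetrix arrays, 3 per group in 6 groups, from SK-N-MC cells infected with the 2F, Pru or CTG strain of Toxoplasma gondii or left uninfected beside each strain. Total RNA was amplified into cRNA and biotinylated with the Affymetrix whole-transcript sense protocol, per the labels' protocols. The deposited values are log2 signals per probe set. The submitters' processing notes name RMA, a background correction and summary method for Affymetrix arrays, together with the Partek software and the human build hg18, without versions or order. Filters were not given in the sources used here. The scale was read from the values, which ran from 2.19 to 14.2 with none missing. The series design text states that each strain's experiments were done on 3 occasions with duplicates, but no label ties an array to an occasion, so p-values measure the spread between these arrays, which may be partly technical.

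Groups and replicate numbers came from the sample titles. Genes were taken from the platform's probe annotation, with symbols updated through gene identifiers to the names of assembly GRCh38.p14. Of 147476 probe sets, 21564 had 1 gene symbol (17475 genes, 1.23 probe sets per gene), and 21490 of these had an identifier in the reference table. Another 4314 had several symbols and were not named, and 121598 were not listed with a gene, which does not mean that they lack one. Where a gene had several probe sets, its value is that of the probe set with the highest mean signal. No coordinates were used.

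All 18 arrays were fitted in 1 limma model with a mean per group, so that the groups shared 1 estimate of spread with 12 residual degrees of freedom (limma 3.58.1, R 4.3.3). Contrasts gave infected minus uninfected for each strain, differences of these between strains, their mean over strains, and differences between uninfected groups. An F test asked for a change with any strain. Moderated tests were adjusted by Benjamini-Hochberg within each contrast over all probe sets, with a threshold of 0.05. No low-signal filter was applied. The number of arrays limits the precision.

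A set of 35 gene lists was fixed before the data were examined, and 1047 of their 1231 genes were measured. They were tested with camera, which compares a list with other genes, at a preset correlation of 0.01, and again with an estimated correlation, under which no list passed in any contrast. The fry test, which asks whether a list's genes move one way without comparing them with other genes, was also run. Lists of macrophage, lymphocyte, astrocyte and oligodendrocyte markers stood for other cell types.

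Named genes followed a rule fixed before the data were examined. For each strain the rule took the 6 highest and 6 lowest changes among genes past the threshold whose infected arrays all lay beyond the uninfected ones, the 3 members with the smallest p of each of 5 lists with the smallest camera p, and 8 genes named in advance, of which 6 were measured and 2 were not analysed here. It took up to 4 genes per difference between strains, or 2 where none passed, and the 6 highest and 6 lowest changes of the pooled contrast. VIPR2 and the unlisted probe sets named by number lay outside this rule and were chosen after their values were seen, as were the further members of lists that are named as having risen.

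The fit was tested on simulated data with each probe set's real mean and normal noise of its moderated variance, equal on all arrays. In these data 50 of 147476 probe sets were changed by each of several amounts in the 2F comparison. It recovered 22% of changes of 0.5 on the log2 scale, 74% of changes of 1, 76% of changes of -1 and 96% of changes of 2, with 6 false calls among 140. A list raised by a known amount was recovered and 0 of the other lists were called. The simulated genes were independent of each other, so this run cannot show how camera behaves where genes are correlated. Real arrays had unequal spread, with array weights from 0.384 to 1.85, so the rates of recovery and of false calls may not hold for them. In the real arrays, other splits of the 6 arrays of a strain called a median of 10 lists for 2F, 9 for Pru and 1 for CTG.

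Alternatives were a trended robust prior, only the arrays compared, the replicate number as a block or random effect, 9 infected against 9 uninfected arrays with strain as a block, array weights, renewed quantile normalization, median centring, removal of the dimmest 33.3% of probe sets, genes alone, no moderation, other thresholds and leaving out each array. Removal of the 4 arrays of lowest weight and the array median as a covariate were added after the data were seen.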

Results

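The human neuroepithelioma line SK-N-MC was infected with tachyzoites, the fast-dividing form, of 1 of 3 strains of the parasite Toxoplasma gondii, and host RNA was measured on Affymetrix arrays 20 hours later. The strains were 2F, Pru and CTG. The cells had been deprived of serum for 2 days and were infected at a multiplicity of 3 parasites per cell. Each strain had 3 arrays of infected cells and 3 arrays of its own uninfected cells, 18 arrays in all in 6 groups. The deposited values are log2 signals of 147476 probe sets, the units the array table lists. Of these, 21564 were listed with 1 gene, 4314 with several and 121598 with none. Array medians lay between 3.28 and 3.46, and the correlation between any 2 arrays lay between 0.946 and 0.983. The number of arrays limits the precision. Adjusted p-values are Benjamini-Hochberg values from limma's moderated test over all probe sets, with a threshold of 0.05.

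The first comparison asked how the host cells changed with each strain. In cells infected with 2F, some immediate-early genes, the first genes transcribed after growth factor or stress signals, rose. EGR1, a zinc finger transcription factor of this class, rose from 4.18 ± 0.10 to 7.12 ± 0.26 (log2 signal, mean ± SD, n = 3), a 7.68-fold increase (log2 change 2.94, SE 0.38, adjusted p = 0.00344 in limma). FOS, a subunit of the AP-1 transcription factor, rose 4.07-fold and EGR3, a relative of EGR1, rose 4.05-fold. ARC, a regulator of synaptic strength, rose 1.93-fold and DUSP5, a phosphatase that acts on ERK, rose 1.94-fold. Of 39 measured members of the immediate-early list, 9 rose, 0 fell and 30 did not pass the threshold. The other members that rose were CCN1, EGR4, IER2 and SRF. Adjusted over the list alone, 15 rose and 0 fell. The list moved up against other genes (camera adjusted p = 1.97e-11, adjusted p = 0.345 with an estimated correlation).

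ULBP1, a ligand of the natural killer cell receptor NKG2D, rose 7.48-fold (log2 change 2.90, SE 0.44, adjusted p = 0.0115). A2M, a secreted protease inhibitor, rose 5.21-fold (log2 change 2.38, SE 0.19, adjusted p = 2.7e-05). IL7R, the interleukin-7 receptor chain, rose 3.14-fold (log2 change 1.65, SE 0.15, adjusted p = 0.000111). A2M, IL7R and EGR3 started from a low signal. They lay at 3.45, 3.27 and 3.53 in uninfected 2F cells, against a median of 3.35 over all probe sets in uninfected cells. Among 30 measured genes of the NF-kappaB and cytokine list, NFKB1, a subunit of NF-kappaB, and PTGS2, an enzyme of prostaglandin synthesis, rose and 28 did not pass. Adjusted over the list alone, 5 rose and 1 fell (camera adjusted p = 0.00586, adjusted p = 0.52 with an estimated correlation). CXCL8 and CCL2, which encode chemokines, had log2 changes of 0.24 (adjusted p = 0.827) and 0.06 (adjusted p = 0.869). Their levels in uninfected 2F cells were also low, 3.65 and 3.56.

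Several of these calls were lost when only the 6 arrays of 2F were used, with an adjusted p of 0.0658 for EGR3, 0.0616 for ARC, 0.0771 for DUSP5, 0.135 for IL7R and 0.212 for ULBP1. That of FOS was lost with the array median as covariate (0.054). Single arrays ended the calls of FOS and ULBP1. Without the third infected 2F array the adjusted p was 0.0901 for FOS and 0.0844 for ULBP1, without the second uninfected 2F array 0.0576 for FOS, without the first 0.0525 for ULBP1, and without the third 0.0771 for FOS and 0.0632 for ULBP1.

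The largest falls with 2F were smaller than the largest rises. TMT1A fell by 1.16 on the log2 scale (SE 0.20, adjusted p = 0.024) and VANGL1, a planar cell polarity protein, fell by 1.16 (SE 0.21, adjusted p = 0.0352). The 3 other probe sets of VANGL1 were not called, with log2 changes of -0.14, -0.50 and -0.65. ZNF217, a zinc finger transcription factor, fell by 1.02, and the non-coding RNA LINC00294 fell by 0.98. CTCFL, a relative of the insulator protein CTCF, fell by 0.75, and TTLL6, a tubulin glutamylase, fell by 0.73. Without the third infected 2F array these adjusted p-values were 0.144 for TMT1A, 0.2 for VANGL1, 0.144 for ZNF217, 0.205 for LINC00294, 0.0531 for CTCFL and 0.109 for TTLL6, and without the third uninfected 2F array 0.128, 0.187, 0.148, 0.201, 0.0905 and 0.1. Other single arrays also ended the calls of TMT1A, VANGL1, ZNF217, LINC00294 and TTLL6. From the 6 arrays of 2F alone none of these falls passed, nor did that of PRC1 (adjusted p = 0.407, 0.238, 0.412, 0.357, 0.338 and 0.36 in the order above, and 0.388). Of 40 measured genes of the G2 and mitosis list, PRC1, which bundles microtubules of the dividing spindle, fell by 0.53 (adjusted p = 0.0146), 0 rose and 39 did not pass. Adjusted over the list alone, 3 fell. The adjusted p of PRC1 was 0.0575 and 0.0961 without the first or the third infected 2F array, and 0.0631 and 0.0987 without the first or the third uninfected one. DLGAP5 and CDK1 had log2 changes of -0.32 and -0.37 (adjusted p = 0.211 and 0.227, and 0.0426 and 0.0495 tested among genes alone). The list moved down (camera adjusted p = 1.29e-08, adjusted p = 0.502 with an estimated correlation). The same direction was found for 38 measured replication-dependent histone genes (mean log2 change -0.28, camera adjusted p = 1.76e-08, adjusted p = 0.345 with an estimated correlation). Their mean was -0.18 without the third infected 2F array (camera adjusted p = 2.28e-06). None of the 38 passed over all probe sets, while 12 fell and 1 rose adjusted over the list alone. H3C3 had a log2 change of 0.78, H4C9 of -0.47 and H2AC4 of -0.90 (adjusted p = 0.0915, 0.155 and 0.17, and 0.0204, 0.0337 and 0.0422 tested among genes alone). H3C3 passed at 0.00559 and 0.0293 without the second or the third infected Pru array, and H2AC4 at 0.0201 without the second infected 2F array. The list of nuclear genes of oxidative phosphorylation moved down (mean log2 change -0.13, camera adjusted p = 0.000423, adjusted p = 0.558 with an estimated correlation), with 0 of 40 members past the threshold and 0 adjusted over the list alone. Without the third infected 2F array its mean was -0.04 (adjusted p = 0.202) and without the second uninfected one -0.20. COX8A, NDUFB10 and NDUFB5 had log2 changes of -0.36, -0.26 and -0.35, the last 2 at -0.16 and -0.23 without the third infected 2F array, and NDUFB5 at -0.53 without the second. A list of ribosome biogenesis genes and MYC targets, called the ribosome biogenesis list here, moved up (mean log2 change 0.23, camera adjusted p = 9.11e-09, adjusted p = 0.425 with an estimated correlation). The mean was 0.12 without the second uninfected 2F array. None of its 32 members passed over all probe sets, and 5 rose adjusted over the list alone. Log2 changes were 0.42 for POLR1B, 0.34 for TFB2M and 0.30 for NOP14 (0.19 without the second uninfected 2F array). The first 2 passed tested among genes alone (adjusted p = 0.0446 and 0.0447).

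In total 300 probe sets were higher and 38 lower with 2F. Of these, 40 genes were higher and 14 lower, each counted by its brightest probe set, and 246 of the higher probe sets had no gene listed. Probe sets with no gene made up 78.4% of the calls and 82.5% of all probe sets. The count was 221 and 110 without the first or the third infected 2F array, 209, 207 and 123 without the first, the second or the third uninfected 2F array, and 567 without the second infected Pru array. It was 224 without the 4 arrays of lowest weight, 159 with the array median as covariate and 92 from the 6 arrays of 2F alone. Tested among genes alone, 204 genes were higher and 320 lower.

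**Figure D1:**
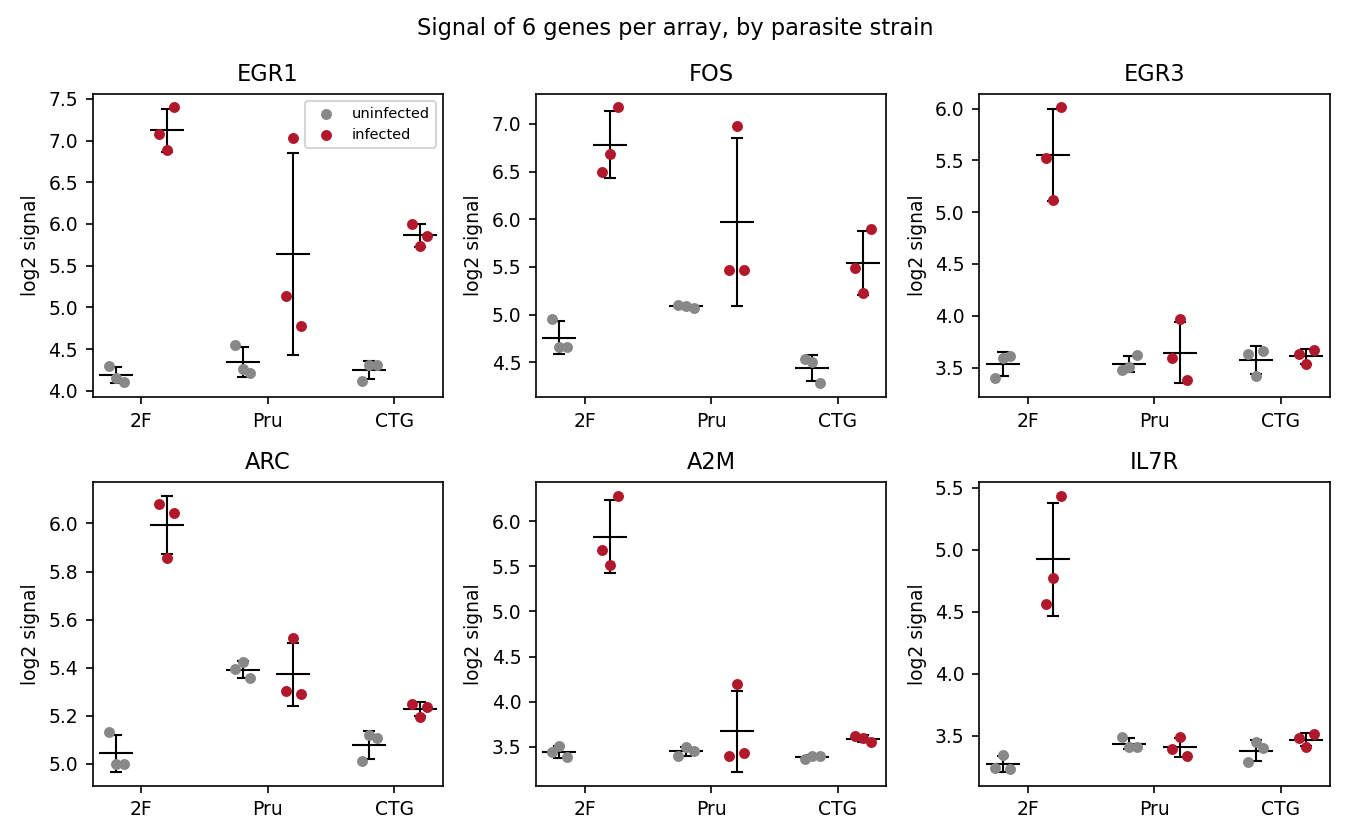
Log2 signal (vertical axis) of EGR1, FOS, EGR3, ARC, A2M and IL7R on each array, by strain (horizontal axis), with uninfected arrays in grey, infected arrays in red and bars for the mean ± SD of 3 arrays. The infected 2F arrays lie above the uninfected 2F arrays in all 6 panels, and 1 infected Pru array reaches 7.03 for EGR1 and 6.98 for FOS.

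In cells infected with Pru, few named genes passed the threshold. TAS2R39, listed as a bitter taste receptor, rose 2.13-fold from 3.66 ± 0.16 to 4.75 ± 0.29 (SD, n = 3, adjusted p = 0.0332 in limma). This call was lost without each of 11 single arrays, with an adjusted p of up to 0.207 without the third uninfected Pru array, and it was lost from the 6 arrays of Pru alone (0.536). A probe set listed with VIPR2, a receptor of vasoactive intestinal peptide, rose 2.67-fold (log2 change 1.42, SE 0.11, adjusted p = 5.49e-05), a call lost from the 6 arrays of Pru alone (0.276). VIPR2 was singled out after its values were seen, and its brighter probe set had a log2 change of 0.11 (adjusted p = 1). EGR1 had a log2 change of 1.30 (SE 0.38, adjusted p = 0.768) with an SD of 1.21 between the infected arrays, and FOS of 0.89 (adjusted p = 0.911). Without the second infected Pru array they were at 0.61 and 0.38. The immediate-early list moved up in Pru (camera adjusted p = 0.011, adjusted p = 0.96 with an estimated correlation), with 0 of 39 members past the threshold and SRF at 0.23. Its adjusted p was 0.875 without the second infected Pru array (mean log2 change 0.01, against 0.10) and 0.115 without the third uninfected one.

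The list of hypoxia-responsive genes moved up with Pru (mean log2 change 0.15, camera adjusted p = 1.11e-06, adjusted p = 0.835 with an estimated correlation). None of its 23 members passed the threshold. PDK1, a kinase that inhibits pyruvate dehydrogenase, had a log2 change of 0.73 (adjusted p = 0.806), and KDM3A and VEGFA of 0.31 and 0.24. The mean of this list was 0.06 without the second infected Pru array (adjusted p = 0.092), 0.23 without the first and 0.10 without the first uninfected one. Without the second infected Pru array PDK1 was at 0.46 and KDM3A at 0.18. The cholesterol synthesis and uptake list moved up (mean log2 change 0.21, camera adjusted p = 2.64e-05, adjusted p = 0.96 with an estimated correlation), and all 17 measured members had a positive change with none past the threshold. NSDHL, STARD4 and SQLE had log2 changes of 0.21, 0.41 (0.19 without the second infected Pru array) and 0.22. The histone list moved up (camera adjusted p = 0.0164, adjusted p = 0.96 with an estimated correlation), with 1 member past the threshold adjusted over the list alone. Its adjusted p was 0.102 without the third infected, 0.17 without the second uninfected and 0.139 without the third uninfected Pru array. H3C3 was at 0.97 (adjusted p = 0.0968, and 0.00836 without the third infected Pru array), H4C6 at -0.33 and H3C6 at -0.15 (-0.22 and -0.24 without the second infected Pru array, and H3C6 at -0.10 without the first). The G2 and mitosis list did not pass (camera adjusted p = 0.0748), with CDK1 at -0.22, NEK2 at 0.20 and MKI67 at -0.20. It passed without the second infected 2F array (0.0489), the first or the third infected Pru array (1.28e-05 and 0.000185) or the second uninfected Pru array (0.00526), and with the array median as covariate (0.000587), and it changed direction without the second infected Pru array (0.147), where CDK1 was at -0.13 and MKI67 at -0.10. Altogether 44 probe sets were higher and 1 was lower, 42 of the higher ones with no gene listed. The count was 29 without the first or the third uninfected Pru array and 79 without the third infected Pru array, and 2 probe sets passed from the 6 arrays of Pru alone.

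In cells infected with CTG, TAS2R39 rose 3.15-fold (log2 change 1.66, SE 0.17, adjusted p = 0.000579 in limma) and the same VIPR2 probe set rose 3.03-fold. The call of TAS2R39 was lost from the 6 arrays of CTG alone (adjusted p = 0.0971). EGR1 was 4.24 ± 0.11 in uninfected and 5.86 ± 0.13 in infected cells (SD, n = 3), a log2 change of 1.62 (SE 0.38, adjusted p = 0.322). Without the second infected Pru array, which enters this fit through the shared estimate of spread, the adjusted p of EGR1 was 0.000166. EGR1 also passed from the 6 arrays of CTG alone (0.0278), with array weights (0.0491) and without the 4 arrays of lowest weight (0.00252). The immediate-early list moved up (camera adjusted p = 0.0115, adjusted p = 0.621 with an estimated correlation), with 0 of 39 members past the threshold and 5 adjusted over the list alone. Its adjusted p was 0.062 without the third infected and 0.0688 without the second uninfected CTG array. The ribosome biogenesis list moved up (mean log2 change 0.23, camera adjusted p = 4.82e-10, adjusted p = 0.587 with an estimated correlation). None of its 32 members passed over all probe sets, and 14 rose adjusted over the list alone. RRP9 and GRWD1, factors of ribosome assembly, had log2 changes of 0.59 and 0.61, and POLR1C, a subunit of RNA polymerases I and III, of 0.48. The cholesterol list moved down (mean log2 change -0.33, camera adjusted p = 2.42e-06, adjusted p = 0.587 with an estimated correlation). The mean was -0.20 without the first and -0.50 without the second uninfected CTG array. All 17 of its members had a negative change and none passed. HMGCS1, MSMO1 and FDPS, enzymes of sterol synthesis, had log2 changes of -0.84, -0.76 and -0.39 (adjusted p = 0.644, 0.63 and 0.656), with FDPS at -0.24 without the first uninfected CTG array. HMGCS1 was at -0.51 with 2F and 0.50 with Pru (adjusted p = 0.716 and 1). It was at -0.96, -0.23 and -0.33 without the first, the second or the third uninfected 2F array, and at 0.30 without the second infected Pru array.

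The G2 and mitosis list also moved down with CTG (mean log2 change -0.12, camera adjusted p = 5.14e-05, adjusted p = 0.621 with an estimated correlation). The mean was -0.06 without the first uninfected CTG array (camera adjusted p = 0.0251) and -0.19 without the second. PRC1, DLGAP5 and ASPM were at -0.23, -0.22 and -0.28 (ASPM at -0.19 without the first uninfected CTG array). Ribosomal protein genes moved down as a list (camera adjusted p = 0.000193, adjusted p = 0.587 with an estimated correlation). RPL10A and RPS12 were at -0.34 and -0.38, and RPL18 at 0.26. Genes of the endoplasmic reticulum stress response moved down as a list (camera adjusted p = 2e-04, adjusted p = 0.587 with an estimated correlation). CALR, PDIA4 and HSPA5, chaperones of this compartment, had log2 changes of -0.32, -0.43 and -0.33. Both lists also moved down with 2F, with means of -0.13 for ribosomal proteins and -0.11 for the stress response (camera adjusted p = 0.00052 and 0.00355). Without the third infected 2F array these means were -0.04 and -0.07 (0.196 and 0.0278). The histone list moved down with CTG too (mean -0.09, camera adjusted p = 0.008), and less without the first uninfected CTG array (-0.05, 0.0896). None of these passed with an estimated correlation. Altogether 49 probe sets were higher and 3 lower, 47 of the higher ones with no gene listed. The count was 32 and 34 without the first or the second infected CTG array, 30 and 34 without the first or the third uninfected CTG array, and 103 without the second infected Pru array. It was 192 without the 4 arrays of lowest weight and 22 from the 6 arrays of CTG alone. MYC had log2 changes of 0.02, 0.08 and 0.04 with 2F, Pru and CTG, and TH, the first enzyme of dopamine synthesis, of 0.10, -0.09 and 0.01, none past the threshold. The signal of TH was low, at 3.72, 3.77 and 3.79 in the uninfected 2F, Pru and CTG cells.

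**Figure D2:**
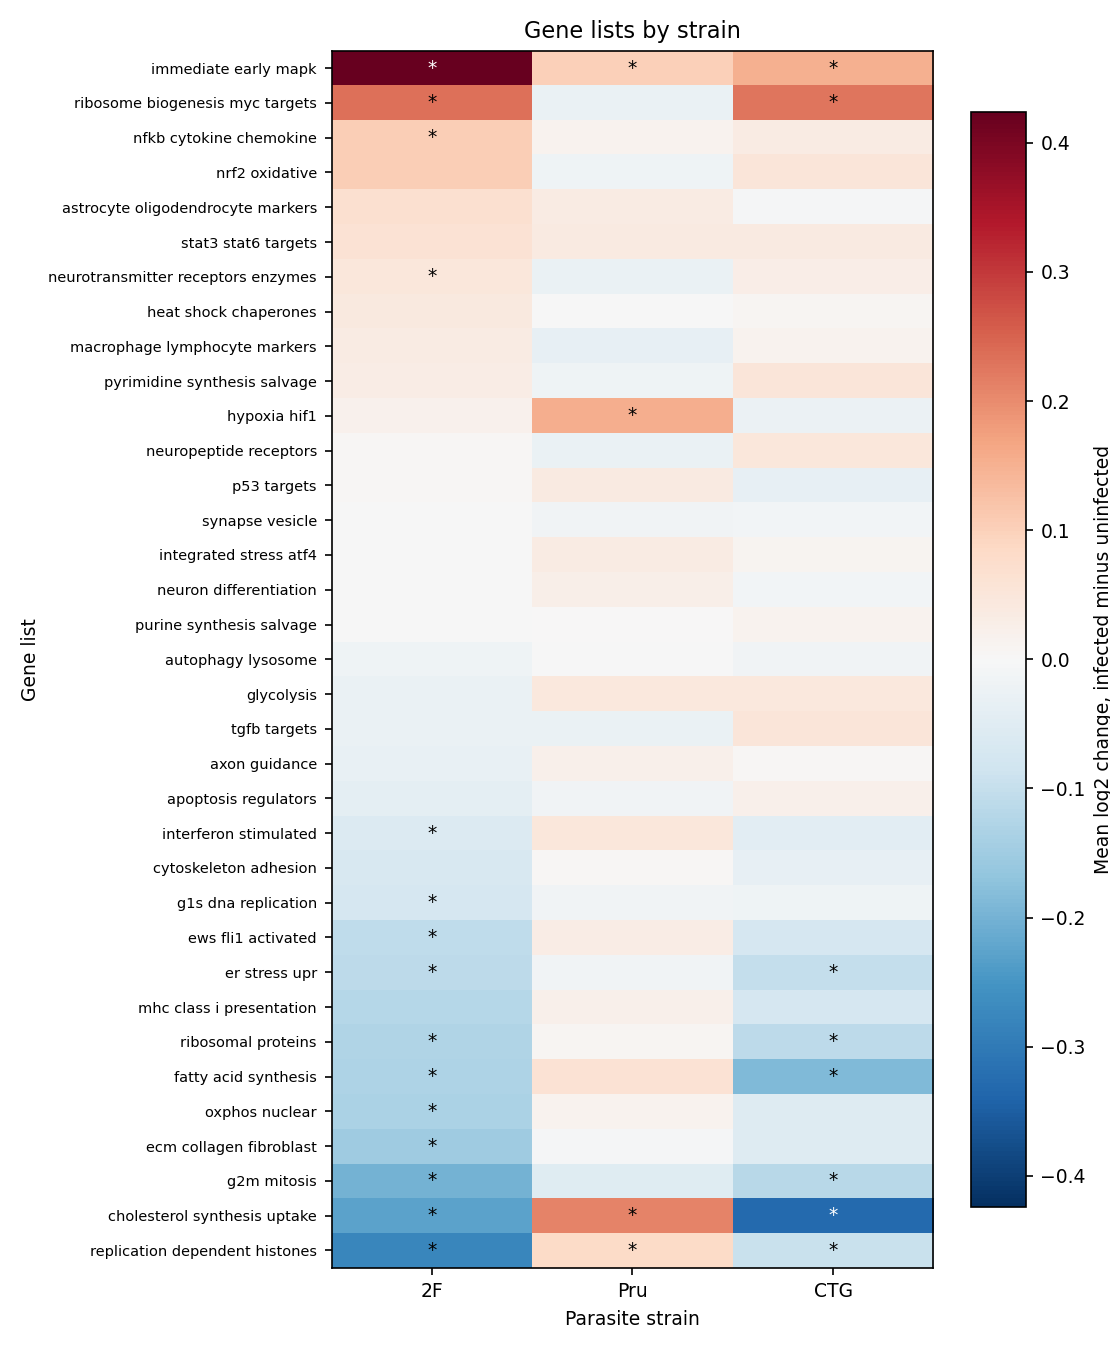
Mean log2 change of 35 gene lists (vertical axis), infected minus uninfected, for each strain (horizontal axis), as colour, with stars where the camera adjusted p with the preset correlation was below 0.05. The immediate-early list has the largest mean change with 2F, 0.42, against 0.10 with Pru and 0.15 with CTG.

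The next comparison asked whether the strains' responses differed, tested as the difference between infection effects. A2M, EGR3, IL7R and ARC rose more with 2F than with Pru. The difference was 2.16 for A2M (log2, SE 0.27, adjusted p = 0.0193), 1.90 for EGR3 (SE 0.26, adjusted p = 0.0337), 1.68 for IL7R (SE 0.22, adjusted p = 0.0234) and 0.97 for ARC (SE 0.12, adjusted p = 0.0149), from limma with n = 3 per group. A2M and EGR3 also rose more with 2F than with CTG, by 2.18 (adjusted p = 0.032) and 1.98 (adjusted p = 0.0419). The difference in EGR1 was 1.64 between 2F and Pru and 1.32 between 2F and CTG (SE 0.54 each, adjusted p = 0.653 and 0.994). Between Pru and CTG no gene passed. The 2 smallest p-values were those of the non-coding RNAs LINC00462, with a difference of -1.44 (adjusted p = 0.305), and NFYC-AS1, with -1.22 (adjusted p = 0.567). Counting all probe sets, 8 were higher and 2 lower with 2F than with Pru, 4 higher and 1 lower than with CTG, and 2 were higher with Pru than with CTG. Each call of a named gene was lost when the comparison used its own arrays alone, with adjusted p-values of 0.177 for ARC, 0.204 for A2M, 0.204 for IL7R and 0.21 for EGR3 between 2F and Pru, and of 0.0747 for A2M and 0.213 for EGR3 between 2F and CTG. Each was also lost without single arrays, among them the third uninfected 2F array (0.0534 for ARC, 0.0759 and 0.117 for A2M, 0.0832 for IL7R, 0.0832 and 0.117 for EGR3).

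The counts of these differences moved with single arrays. Between 2F and Pru the count was 23 without the second and 5 without the first infected Pru array, 6 and 4 without the first or the third uninfected 2F array, and 4, 4 and 6 without the first, the second or the third uninfected Pru array. Between 2F and CTG it was 10 without the second infected 2F array, 11 without the second infected Pru array, and 3 without any 1 of the 9 uninfected arrays or of the first and second infected CTG arrays. Between Pru and CTG it was 7 without the second uninfected 2F array and 4 without the third uninfected CTG array.

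Among gene lists, immediate-early genes moved up more with 2F than with Pru (camera adjusted p = 1.15e-07, adjusted p = 0.43 with an estimated correlation) and than with CTG (camera adjusted p = 1.14e-10, adjusted p = 0.593 with an estimated correlation). Against Pru, 2 of 39 members passed and 9 adjusted over the list alone, and against CTG 1 and 7. The cholesterol list differed between Pru and CTG (camera adjusted p = 8.33e-10, adjusted p = 0.569 with an estimated correlation). It also differed between the uninfected cells of these strains, with a mean of -0.29 for Pru minus CTG (camera adjusted p = 6.99e-06, adjusted p = 0.798 with an estimated correlation), which was -0.16 without the first and -0.46 without the second uninfected CTG array. The ribosome biogenesis list was 0.23 higher in the uninfected Pru cells than in the uninfected CTG cells (camera adjusted p = 1.26e-11, adjusted p = 0.502 with an estimated correlation). No single probe set passed in limma between any 2 sets of uninfected cells. At an unadjusted p under 0.05 there were 5481 (3.72%) for 2F against Pru, 6254 (4.24%) for 2F against CTG and 7385 (5.01%) for Pru against CTG. These shares are near or under the 0.05 expected where nothing differs. For infected against uninfected cells they were 9.04% with 2F, 4.88% with Pru and 7.08% with CTG.

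Over all strains pooled, EGR1 rose 3.87-fold (log2 change 1.95, SE 0.22, adjusted p = 0.000505), FOS 2.53-fold and ULBP1 2.80-fold. The probe set listed with TAS2R39 rose 2.76-fold from a low signal. Its level was 3.55, 3.66 and 3.45 in the uninfected 2F, Pru and CTG cells, against a median of 3.35 over all probe sets. Whether its rise came from host RNA was not tested. IBA57, which takes part in iron-sulphur cluster assembly, rose 1.93-fold and A2M 1.91-fold. None of the 5 other probe sets of IBA57 was called (log2 changes of at most 0.55), and its call was lost without the 4 arrays of lowest weight (adjusted p = 0.0938). A2M changed by 2.38 with 2F, 0.22 with Pru and 0.20 with CTG. The largest falls were in TMT1A, by 0.69, LINC00294, by 0.63, ZNF217, by 0.59, TTLL6, by 0.43, CTCFL, by 0.40, and APAF1, a component of the apoptosome, by 0.35 (adjusted p = 0.0261). In a fit of 9 infected against 9 uninfected arrays with strain as a block, the calls of A2M (adjusted p = 0.285), ULBP1 (0.122), TMT1A (0.13), LINC00294 (0.13), ZNF217 (0.223), TTLL6 (0.0993), CTCFL (0.129) and APAF1 (0.201) were lost. The call of APAF1 was lost without each of 12 single arrays, with an adjusted p of up to 0.074 without the first uninfected CTG array. Those of ULBP1 (0.051) and ZNF217 (0.0507) were lost without the third uninfected CTG array, and that of CTCFL (0.0503) without the third uninfected 2F array. Immediate-early genes that rose numbered 11 of 39, with CCN2 and JUNB added to those that rose with 2F (camera adjusted p = 4.42e-10, adjusted p = 0.397 with an estimated correlation), and 14 rose adjusted over the list alone. SRM, a spermidine synthase, was the 1 of 32 members of the list of ribosome biogenesis genes and MYC targets that rose. In all 421 probe sets were higher and 33 lower, with 51 genes higher and 13 lower. In a test for a change with any strain, 317 probe sets passed, with 187 without the third infected and 186 without the third uninfected 2F array.

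Most probe sets that rose with every strain had no gene listed. With all 3 strains 37 probe sets were higher, 35 of them with no gene, where 82.5% of all probe sets had none. The other 2 were those listed with TAS2R39 and VIPR2. Their median level in uninfected cells was 3.01, against 3.35 over all probe sets, and their median log2 change was 1.65 with 2F, 1.39 with Pru and 1.47 with CTG. The probe set 2639847 rose by 6.04 with 2F, 5.22 with Pru and 4.98 with CTG (log2, SE 0.38 each), and its Pru call was lost from the 6 arrays of Pru alone (adjusted p = 0.188). The probe set 3057260 rose by 4.51, 4.34 and 4.55 (SE 0.21 each). Of the probe sets higher with 2F and with Pru, 39 were shared, against 0.0895 for independent lists. For 2F and CTG 49 were shared, against 0.0997, and for Pru and CTG 37, against 0.0146. From only the arrays compared these counts were 1, 17 and 1. The count for 2F and Pru was 25 and 24 without the first or the third uninfected Pru array. The count for 2F and CTG was 89 without the second infected Pru array, 32 and 30 without the first or the second infected CTG array and 30 without the first uninfected CTG array, and that for Pru and CTG was 23 without the third uninfected Pru array. Each strain had its own uninfected arrays, but the 3 contrasts shared 1 estimate of spread per probe set. Calls with different strains are therefore linked, and the counts for independent lists can be too low a reference. Across genes, which are not independent replicates, log2 changes with 2F correlated with those with CTG at r = 0.53 and with those with Pru at r = 0.05, and those with Pru correlated with those with CTG at r = -0.08. These correlations were not computed with the array median as covariate, so a shared response was not told apart from shifts of whole arrays.

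**Figure D3:**
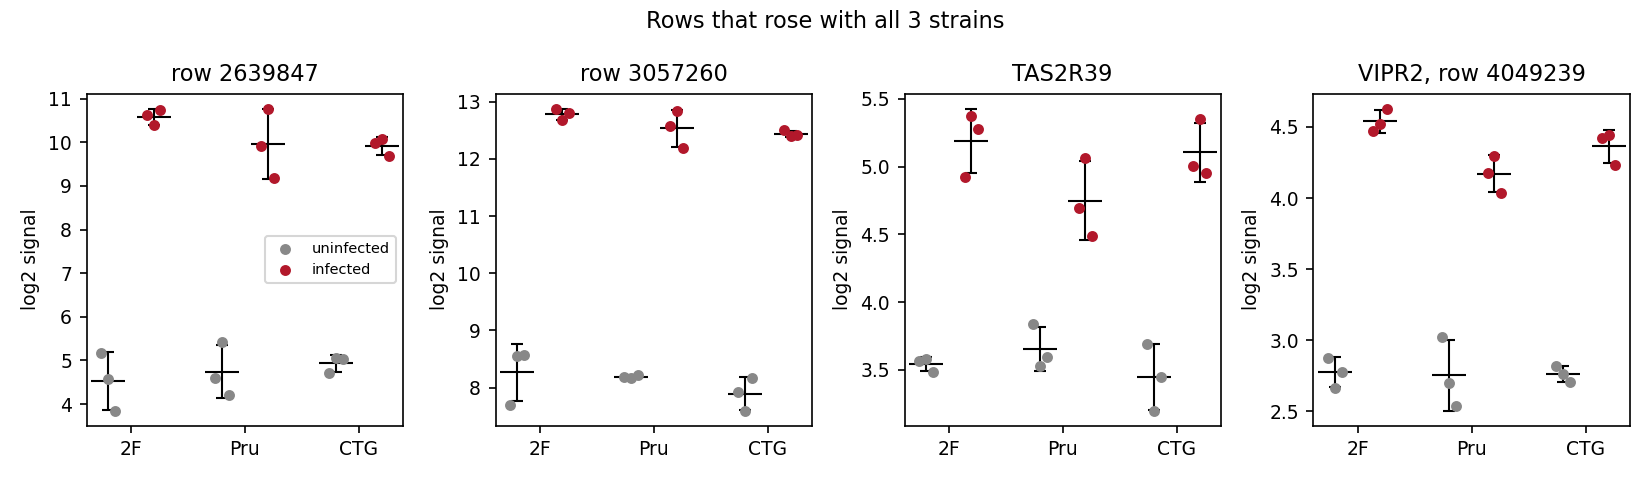
Log2 signal (vertical axis) of 4 probe sets that rose with every strain, by strain (horizontal axis), with uninfected arrays in grey, infected arrays in red and bars for the mean ± SD of 3 arrays. All infected arrays lie above all uninfected arrays in each panel.

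**Figure D4:**
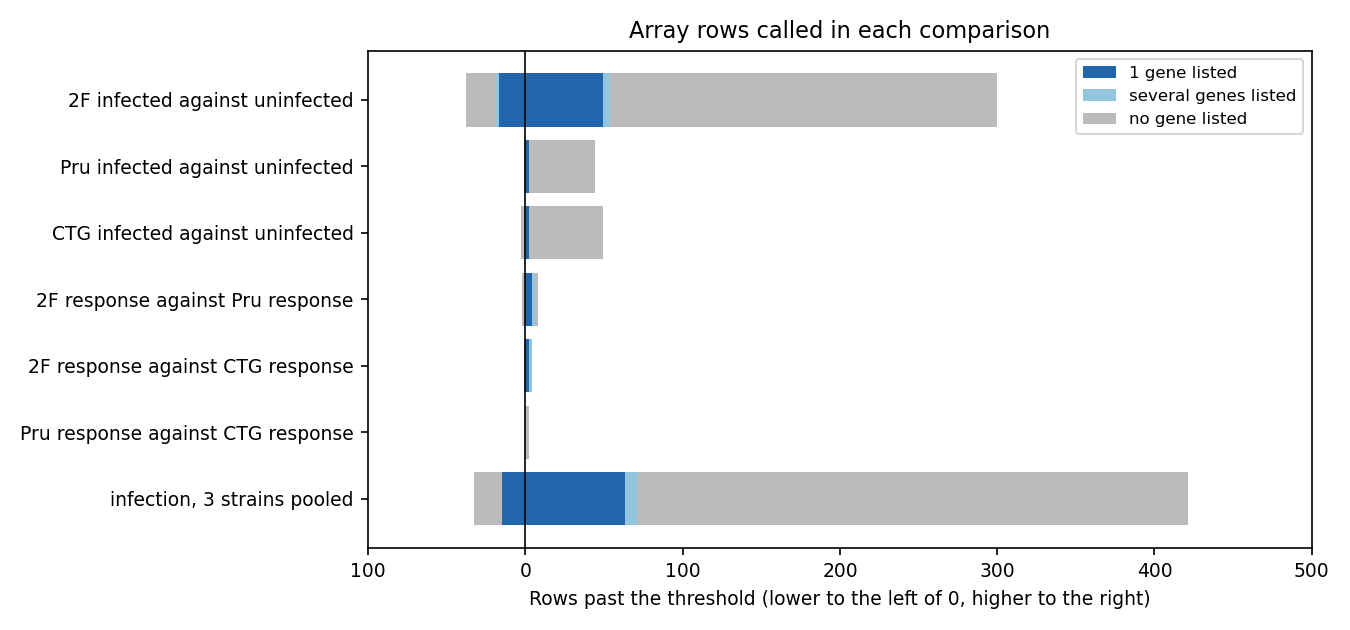
Number of probe sets past the threshold (horizontal axis, lower to the left and higher to the right of 0) in 7 comparisons (vertical axis), split by whether 1 gene, several or none is listed. With 2F, 300 are higher and 38 lower, and probe sets with no gene listed make up 78.4% of the calls, against 82.5% of all probe sets.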

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

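The tests of parasite signal and of the levels in uninfected 2F cells were chosen after the results were seen.

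Some responses to infection differed between strains past the threshold in limma's test of the difference itself, given here on the log2 scale. A2M differed by 2.16 between 2F and Pru and by 2.18 between 2F and CTG, and EGR3 by 1.90 and 1.98. ARC differed by 0.97 and IL7R by 1.68 between 2F and Pru. A pair of probe sets listed with several genes were higher with 2F, by 3.82 and 1.88 against Pru and by 3.75 and 1.87 against CTG. Of the probe sets with no gene listed, 2 had log2 changes of 1.92 and 2.01 with Pru. Their differences were -1.97 and -1.97 for 2F minus Pru, and 1.95 and 2.05 for Pru minus CTG. Another 2 were higher with 2F than with Pru, by 2.74 and 0.92, and 1 differed by -1.32 for 2F minus CTG. For the splits, strain labels were redrawn among the infected and, separately, among the uninfected arrays. The real 10 of 2F against Pru were reached or passed in 3 of 100, the real split included (highest other 15). The real 5 of 2F against CTG were reached or passed in 2 of 100 (highest other 7). These shares are under 0.05 but were not adjusted over the split tests, and some other splits gave more than the real count. They argue against chance without excluding it. For Pru against CTG 11 of 100 gave as many as the real 2 (highest other 3), so chance was not excluded.

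Of 39 immediate-early genes 9 rose with 2F (list adjusted p = 0.345 with an estimated correlation), and low levels in uninfected 2F cells are argued against, since the mean log2 change of the 9 called genes was 1.33 against the 6 uninfected arrays of the other strains and 1.40 against the 2F ones. Array background as the whole cause is argued against, since the mean change was 1.24 with the array median as a covariate and 7 of the 9 genes stayed past the threshold. More parasite signal on the 2F arrays stays open: over the 6 infected Pru and CTG arrays an index of 80 unlisted probe sets, chosen on 2F arrays alone, followed the mean of the 9 genes (r = 0.883, exact permutation p = 0.0292, rho = 0.771, exact permutation p = 0.103), but without the 2 farthest arrays r was -0.117, so the relation rests on those. A line through the 6 arrays gave 0.8 at the mean 2F index, against a 2F mean of 1.36 (SD 0.211). The 80 probe sets and the 9 genes were both picked for having risen with 2F, which can raise both 2F values, so the gap from the line cannot decide. Within strains, on 3 arrays each and too few for a correlation, the relation ran in opposite directions for Pru and CTG. The strain itself, which the design names, stays open as well and was not tested apart from parasite signal.

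Splits of the 6 arrays of each strain number 10, too few for a share under 0.05. As many probe sets as the real 338 with 2F came in 1 of 10 (highest other 20), as many as the real 45 with Pru in 1 of 10 (highest other 2) and as many as the real 52 with CTG in 1 of 10 (highest other 1). Between uninfected groups all 10 of 10 gave at least the real 0, with highest other counts of 1, 0 and 0. For the pooled comparison 1 of 100 splits, the real one, gave as many as 454 (highest other 68). For the test of any strain 1 of 100, again the real one, gave as many as 317 (highest other 18). Both shares argue against chance.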

How the results depend on the processing

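The alternatives without the 4 arrays of lowest weight and with the array median as a covariate were chosen after the data were seen.

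EGR1 and A2M passed with 2F under all 30 alternatives, each array left out included. Unless the construction of an alternative shows it (fewer arrays, fewer probe sets tested, another threshold), the cause was not tested. Counts outside 1.5 times the reported ones are given by setting, in the order 2F, Pru and CTG infection, then the differences 2F against Pru, 2F against CTG and Pru against CTG, then pooled.

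From only the arrays compared, the counts were 92, 2, 22, 2, 1 and 1, and the shared probe sets 1 for 2F and Pru, 17 for 2F and CTG and 1 for Pru and CTG. With array weights, Pru gave 76, CTG 114, 2F against Pru 23, the uninfected Pru and CTG arrays 2, the test for any strain 476 and the overlap of 2F and CTG 81. The weights ended the calls with 2F of TMT1A (adjusted p = 0.0691), VANGL1 (0.0574), ZNF217 (0.0636) and LINC00294 (0.06). Among genes alone 2F gave 524, Pru 0, CTG 10, Pru against CTG 0, the uninfected Pru and CTG arrays 1, and the overlaps were 0, 4 and 0. Without the dimmest probe sets Pru against CTG gave 1. Without moderation 2F against CTG gave 3, any strain 194 and the overlap of Pru and CTG 23. Infected arrays compared directly gave 48 for 2F against Pru and 13 for 2F against CTG. Without the 4 arrays of lowest weight the counts were 224 for 2F, 192 for CTG, 32, 8 and 26 for the differences, 1 for the uninfected Pru and CTG arrays, and 25 and 76 for the overlaps of 2F with Pru and CTG. Of the 54 genes called with 2F, 20 remained there and 22 with the array median as covariate, where 2F gave 159 and Pru 80. With a 2-fold threshold 2F gave 181 and pooled 121, and with 1.5-fold pooled gave 276. At an adjusted p of 0.01 the counts were 126 for 2F, 33 for CTG, 4 and 3 for the differences from 2F and 251 pooled, and at 0.10 they were 606 for 2F, 69 for Pru, 21 for 2F against Pru and 708 pooled.

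With the replicate number as a block the counts were 104, 16, 19, 2, 1, 1 and 212, any strain gave 102, the overlaps were 14, 18 and 13, and 3 lists passed for 2F against CTG. The block also ended the calls of FOS with 2F (adjusted p = 0.0972), TAS2R39 with CTG (0.0721) and Pru (0.402), PRC1 (0.175) and the 6 largest falls with 2F (0.148 to 0.202), the differences between 2F and Pru of ARC (0.31), A2M (0.31), IL7R (0.388) and EGR3 (0.37) and between 2F and CTG of A2M (0.34) and EGR3 (0.361), and the pooled calls of TMT1A (0.111), LINC00294 (0.0882), TTLL6 (0.132), ZNF217 (0.195), CTCFL (0.187) and APAF1 (0.186). Of the 54 genes called with 2F, 13 remained, and of the 4 and 2 genes called in the differences from Pru and CTG, 0. As a random effect it gave 3 for 2F against CTG and ended the differences between 2F and Pru of EGR3 (0.054) and between 2F and CTG of A2M (0.0509) and EGR3 (0.0677). It also ended the calls with 2F of VANGL1 (0.0525) and LINC00294 (0.0545). Only 3 of 9 infected arrays correlated best with the uninfected array of their own number, so the arrays were not treated as pairs.

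Lists past the threshold numbered 0 in all 7 comparisons with an estimated correlation. With fry they were 3 for 2F, 0 for Pru, CTG and the differences, and 3 pooled, and in either direction 30 for 2F, 0 for Pru, 5, 1 and 0 for the differences and 26 pooled. For 2F against CTG, 2 passed with centred arrays, 2 without the 4 arrays and 2 with the covariate. Without the 4 arrays 8 passed for Pru and 12 for Pru against CTG, and with the covariate 7 for 2F, 9 for 2F against Pru and 6 pooled.

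Directions turned for small changes that had not passed. With array weights the log2 changes were -0.0080 for MYC in 2F, -0.0034 for TH in CTG and -0.00792 for EGR3 in CTG. After quantile normalization they were -0.018 for CCL2 in 2F and -0.0047 for TH in CTG, and with centred arrays -0.049 for MYC and -0.0090 for CCL2 in 2F and -0.020 for TH in CTG. Without the 4 arrays they were -0.012 for MYC in 2F, -0.12 for CXCL8, -0.047 for EGR3 and -0.037 for A2M in Pru, and -0.032 for TH and -0.041 for EGR3 in CTG, and the G2 and mitosis list in Pru turned at an adjusted p of 0.107. With the covariate they were -0.061 for CXCL8 in 2F and -0.019 for CXCL8, -0.018 for TH and -0.045 for EGR3 in CTG.

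Leaving out each array in turn gave 110 to 567 for 2F (lowest without the third infected 2F array, highest without the second infected Pru array), 29 to 79 for Pru, 30 to 103 for CTG, 4 to 23, 3 to 11 and 2 to 7 for the differences, 186 to 456 for any strain and 0 to 1 for the uninfected Pru and CTG arrays, where the 1 came without the second uninfected CTG array. The overlaps were 24 to 58, 30 to 89 and 23 to 41. Lists numbered 2 to 6 for Pru, 1 to 6 for 2F against CTG, 6 to 13 for Pru against CTG and 7 to 11 pooled. Log2 changes ran from -0.031 to 0.053 for MYC in 2F, -0.12 to 0.53 for CXCL8, -0.070 to 0.0061 for IL7R, -0.047 to 0.25 for EGR3, -0.096 to 0.021 for ARC and -0.037 to 0.36 for A2M in Pru, and -0.032 to 0.041 for TH and -0.041 to 0.080 for EGR3 in CTG. The adjusted p of the G2 and mitosis list in Pru ran from 1.28e-05 to 0.369. Of the values of named genes and some further probe sets with an array left out, 1831 kept direction and side of the threshold. Another 133 lost and 5 gained the call, and 11 changed direction. The tally includes results that had not passed, which could not lose a call. It also includes arrays outside a comparison, whose removal left the log2 change as it was, so it understates how easily calls were lost.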

Other observations

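The tests of unlisted probe sets, of differences between uninfected cultures and of array medians were chosen after the results were seen.

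Further genes rose with 2F that the text has not described. KITLG, the ligand of the receptor KIT, rose by 0.85 (log2, SE 0.11, adjusted p = 0.00377 in limma), LGR5 by 0.78 and ERRFI1, an inhibitor of the EGF receptor, by 0.47. Among falls, MAP2K6, a kinase that activates p38, fell by 0.50, and ITGA5, an integrin chain, fell by 0.55. These genes were chosen after their values were seen. Markers of macrophages and lymphocytes did not pass as a list with 2F, Pru or CTG (camera adjusted p = 0.338, 0.581 and 0.866), nor did astrocyte and oligodendrocyte markers (0.0705, 0.69 and 0.415). Interferon-stimulated genes moved down as a list with 2F (mean log2 change -0.06, camera adjusted p = 0.0477, adjusted p = 0.449 with an estimated correlation) and did not pass with Pru or CTG (0.709 and 0.667), with 0 of 43 members past the threshold each time. The mean with 2F was -0.10 and -0.03 without the first or the second uninfected and -0.03 without the third infected 2F array, and the adjusted p was 0.0567, 0.0947, 0.347, 0.0577, 0.0503 and 0.0502 without the first or the second infected 2F, the second uninfected 2F, the second infected Pru and the first or the third infected CTG array. Their mean and median differed in sign with Pru (0.05 and -0.01) and with CTG (-0.05 and 0.01).

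The second infected Pru array stood apart within its group. Its EGR1 level was 7.03 and its FOS level 6.98, against 5.13 and 4.77 for EGR1 and 5.46 and 5.47 for FOS on the other Pru arrays. Its index of unlisted probe sets was 1.91, against 1.09 and 0.78. EGR3 was 3.96, IL7R 3.49 and A2M 4.19 on this array, below the lowest 2F values of 5.12, 4.56 and 5.51. It also had the lowest array weight, 0.384.

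Some probe sets with no gene listed rose with all 3 strains, and a candidate explanation is parasite RNA binding to their probes. The probe sets listed with TAS2R39 and VIPR2 also rose with all 3 strains, and this explanation was not tested for them. Array background as the whole cause is argued against for the 35 unlisted ones with 2F. Their median log2 change was 1.57 with the array median as covariate, against 1.65 without it (median SE 0.15). It was 1.40 with Pru and 1.41 with CTG, against 1.39 and 1.42 without the covariate, and 34 still passed with all 3 strains. Infected and uninfected arrays differed less in level with Pru and CTG (median log2 change over all probe sets -0.0019 and 0.013, against 0.033 with 2F). The covariate could therefore move the changes with Pru and CTG little. Array background stays open for the 211 unlisted probe sets higher with 2F but not with all 3 strains. Of these, 78 still passed with 2F and the covariate. The median change of the 211 went from 1.12 to 0.998 at a median SE of 0.176 in both fits, and why calls were lost was not tested. Parasite RNA stays open. All 80 probe sets chosen on 2F arrays alone had positive changes with Pru and with CTG. Their concordance over the infected arrays (Kendall's W) was 0.837 for Pru, 0.128 for CTG and 0.188 for 2F, against at most 0.0405 over uninfected arrays. W measures whether the probe sets rank the 3 arrays of a group alike, and it is low where those arrays are similar. The index of these probe sets had an SD of 0.134 over infected CTG and 0.105 over infected 2F arrays, against 0.582 for Pru. The low W with CTG therefore cannot decide. Host transcripts outside listed genes stay open too and were not tested.

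The cholesterol list moved up with Pru and down with CTG (adjusted p = 0.96 and 0.587 with an estimated correlation) and down with 2F (mean log2 change -0.23, camera adjusted p = 0.00986, adjusted p = 0.658 with an estimated correlation), where the mean was -0.19 without the first infected 2F array (adjusted p = 0.0567), and -0.44, -0.11 and -0.13 without the first, the second or the third uninfected one (4.37e-08, 0.248 and 0.234). The ribosome biogenesis list moved up with 2F and CTG (adjusted p = 0.425 and 0.587 with an estimated correlation, and a mean of 0.12 without the second uninfected 2F array) and did not pass with Pru (mean log2 change -0.03, camera adjusted p = 0.69). Array background as the whole cause is argued against for ribosome biogenesis with 2F. Its mean was 1.41 times as large with the array median as covariate (camera adjusted p = 1.64e-17 at the preset correlation). With CTG the means went from 0.23 to 0.27 and from -0.33 to -0.33 (smaller ratio 0.991). Cholesterol with Pru was 0.996 times as large (camera adjusted p = 0.000587). Infected and uninfected arrays differed less in level with these strains (median log2 change over all probe sets 0.013 with CTG and -0.0019 with Pru, against 0.033 with 2F). The covariate could therefore move these means little, and their ratios do not decide. Array background also stays open for cholesterol with 2F. There the mean was 0.971 times as large (-0.22 against -0.23) but no longer passed (camera adjusted p = 0.0592), and why was not tested. Differences between cultures that are not infection are consistent with the values, since the largest difference between 2 uninfected groups was 0.893 times the largest infection change for cholesterol (0.29 between uninfected 2F and Pru cells, and 0.51, 0.18 and 0.19 without the first, the second or the third uninfected 2F array) and 0.976 times for ribosome biogenesis. Splits of the arrays were also counted by lists past the camera threshold. Within strains the 10 splits are too few for a share under 0.05: 9 of 10 gave as many as the real 4 for Pru (highest other 14), 4 of 10 as many as the real 8 for CTG (highest other 12) and 1 of 10 as many as the real 15 for 2F (highest other 13). In the pooled comparison 12 of 100 splits gave as many as the real 11 (highest other 14). For 2F against CTG 66 of 100 gave as many as 5 (highest other 14). For Pru against CTG 35 of 100 gave as many as 7 (highest other 13), so chance was not excluded in these comparisons. For 2F against Pru only the real one of 100 gave as many as 17, but the others reached 15, with a median of 8. This argues against chance without excluding it, and no list passed there with an estimated correlation.

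Principal components were computed on the brightest 33.3% of probe sets only. Array medians correlated with the first component, which held 23.63% of the variance of these probe sets, over the 18 arrays (r = 0.838, permutation p = 2e-05, rho = 0.856, permutation p = 2e-05). Without the 2 farthest arrays r was 0.788. It was 0.779 within infected and 0.902 within uninfected arrays.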
